A study of Drosophila melanogaster with 3 samples.

How the data were processed

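Chromatin immunoprecipitation followed by sequencing (ChIP-seq) had been carried out on whole Drosophila melanogaster embryos aged 0 to 24 hours. The flies carried a transgene for CG11695, a zinc finger gene, fused to enhanced green fluorescent protein (eGFP), and the precipitation used an antibody against GFP. Chromatin was sonicated and fragments of 200 to 800 bp were selected, per the labels. There were 3 biological replicates in 1 group. The accompanying text notes name signal tracks relative to a control, which were not used here. No comparison group and no input library was analysed here, so every test below is against genomic background and not against another condition.

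The files were peak lists on assembly dm6, per the file headers of the accompanying text notes. The aligner and the peak caller are not given in the sources used here. Each list came from the irreproducible discovery rate (IDR) procedure, which compares the ranks of peaks in a pair of peak sets. The signal value of each peak is the authors' own and its scale was not stated, so it was used only to rank and describe peaks within a list. The score deposited with each peak is scaled from the global IDR, and its lowest value in the thresholded lists was 830. The ranked lists deposited by the authors also give −log10 of the global IDR, which reached 0.01 at most in the thresholded lists. Total read numbers were not part of the lists, so the depth of each library is unknown and no counting interval is given.

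The main list was the authors' conservative list. The labels do not say which replicates it compared. The ranked counterpart of each pair list was matched to the replicates by identical peak records. For the main list, 73.7% and 67.4% of the records of the compared sets occurred in the ranked lists of replicates 1 and 3, and 0% in those of the others. For all pair lists these shares were 63.3% to 73.7%. By this match the ranks compared for the main list were those of replicates 1 and 3. The peaks themselves and their signals came from pooled libraries: of the records of each thresholded pair list, 99.8% to 99.9% stood with the same ends, summit and signal in the pooled ranked list, against 0% of each replicate's own list, and the accompanying text notes name alignments of all 3 replicates as sources of the pair lists. Results given as without replicate 3 or without replicate 1 therefore leave that replicate out of the IDR comparison alone, and only the own lists and the signal correlation of single pairs are free of the other libraries. Peaks were kept on the 6 arms 2L, 2R, 3L, 3R, 4 and X, with 1 record per summit. Coordinates are 1-based.

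Many records lay beside a stronger one. In the main list 369 of 4770 records had a stronger record within 250 bp, at a median distance of 203 bp. The stronger record lay at the lower coordinate in 368 of these, and 333 of them carried the same score, so they may be repeated matches of 1 peak. They were kept in the main values, because the list was fixed before the data were examined, and overlap, signal at promoters, location, arms, genes, short sequences, motifs and composition were computed again with such summits merged, which left 4402 peaks.

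Genes and transcription start sites (TSSs) came from the Ensembl annotation BDGP6.54 and sequence from the RefSeq copy of the same assembly. No peak or gene ended beyond the length of its arm. A peak was called a promoter peak when its summit lay within 500 bp of a TSS, and otherwise took the first of 5' UTR, coding exon, 3' UTR, non-coding exon, intron and intergenic. The non-coding exon class was added after the data were seen. Shares were compared with 1000 shuffles of the summits within each arm, leaving out assembly gaps. These permutation tests were two-sided for location and composition, with a smallest possible p of 0.002, and one-sided for overlap, with a smallest possible p of 0.001. Overlap meant 1 bp or more with a peak in the own list of each replicate.

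Peaks per arm were tested with an exact binomial test. Among 13945 protein-coding genes, those with a summit within 500 bp of a TSS were counted in 21 gene lists and at divergent promoters, meaning TSSs within 1000 bp that point away from each other, with Fisher's exact test, two-sided. Of the listed symbols, 3 were not found in the annotation. All sequences of 6 to 8 bases were counted within 50 bp of summits and in flanks at 300 to 400 bp, found on 2L, 2R and 4 and tested on 3L, 3R and X with a one-sided exact McNemar test. A set of 13 known consensus motifs was tested within 100 bp against flanks at 300 to 500 bp, two-sided. Signal at promoters was compared with 100000 permutations. The Benjamini-Hochberg adjustment covered each family of tests, at a threshold of 0.05.

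Named genes were those whose TSS was nearest, within 1000 bp, to the 25 strongest main peaks that overlapped a peak in every replicate's own list, up to 4 members of each gene list by highest signal, and CG11695. The lists, motifs, tests and this rule were fixed before the data were examined. Alternatives covered the threshold, the pooled list, the left-out replicates, the overlap rule, the promoter distance, the gene background, and the windows and controls for sequence. Chosen after seeing the data were a global IDR of 0.001, the merging of summits within 250 bp, the adding back of 126 records past the score threshold that the thresholded list leaves out, for a reason not given in the sources used here, dinucleotide-shuffled control sequences, the test of the overlap between own lists, the moving of peaks to genes drawn with equal chance and the single replicate pairs of the signal correlation.

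The procedures were tested on simulated data. A simulated promoter share of 39.1% was returned as 39.4%, and a share in all lists of 48.4% as 49.8%. No sequence was called at random sites, an implanted sequence led the calls, and 1 of 1 altered gene lists was called. Divergent promoters were called when their genes were drawn 3 times as often as others and not when drawn as often. The software was Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9.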

Results

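The data were lists of genomic sites recovered from chromatin of whole Drosophila embryos that carried CG11695-eGFP, a zinc finger protein tagged with a fluorescent protein, with an antibody against the tag. No input or mock precipitation was analysed here, so sites that come up in any precipitation cannot be separated from sites bound by the protein. There were 3 biological replicates and 1 group. The design asks where chromatin was recovered along the genome, how well the replicates repeated, and which genes and sequences lay at the sites.

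The main list held 4770 peaks, and 17 of the 25 strongest repeated ones were promoter peaks. The peak of highest signal stood 45 bp upstream of a TSS of Ugalt, a UDP-galactose transporter gene (X, 2703693 to 2704061), with a signal value of 2266, and it ranked 1 in the own list of each replicate. CG14100 (3L, 19590449 to 19590784, signal 1583) and PNPase, which encodes a mitochondrial RNA-degrading enzyme (3R, 31404498 to 31404823, signal 1562), followed among promoter peaks. Promoter peaks at the mitochondrial ribosomal protein genes mRpL41 (2R, 15217599 to 15217904) and mRpS10 (3R, 15229375 to 15229686) had signals of 1473 and 1292. Chro, which encodes a chromodomain protein of interbands (3L, 22878729 to 22879065), had 1360. Polr2B, a large subunit of RNA polymerase (3R, 14125497 to 14125927), had 1357, and the glycolytic gene Gapdh2 (X, 15867807 to 15868154) had 1264.

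Further genes with a TSS within 1000 bp of the 25 strongest repeated peaks were Reph, lncRNA:CR44619, CG18549, CenG1A, CG7601, HmgZ, px, Tcs5, ph-p, CG13390 and MFS18. The other 8 of these 25 peaks were 7 intronic and 1 intergenic, and 19 of the 25 had a TSS within 1000 bp. Reph and HmgZ were nearest to intronic peaks, 926 bp and 588 bp from their TSSs. The strongest intronic peak (2L, 6612454 to 6612921, signal 2065) lay 1020 bp from the nearest TSS and ranked 2 in each replicate's own list.

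The replicates' own lists held 2965 ± 382 peaks (SD, n = 3), from 2716 to 3404. Of the main peaks, 1756 (36.8%) overlapped a peak in all 3 own lists, against 0.721% of shuffled positions (permutation p = 0.001, the smallest possible). The main list holds peaks called on pooled libraries of all replicates, so an overlap above that of shuffled positions is built in. The smallest own list was 56.9% as long as the main list. Between replicates, whose own lists each come from 1 library, 61.1% to 79.4% of the peaks of 1 own list overlapped a peak of another, against 1.22% to 1.55% of shuffled positions (permutation p = 0.001 for each of 6 ordered pairs, the smallest possible). Over all peaks of the ranked lists, signals of a pair correlated with Spearman's rho of 0.307 ± 0.0141 and Pearson's r of 0.431 ± 0.0134 on the log2 scale (SD, n = 3 pairs). These values are across peaks, which are not independent replicates. For peaks past the threshold rho was 0.726 ± 0.0260 (SD, n = 3 pairs), but the threshold itself keeps peaks of similar rank in both replicates, so a higher value is built in. The count of 4770 included 369 records beside a stronger record, most with the same score, and these may be repeats of 1 peak and not separate sites. Merging left 4402, because 1 of the 369 lay within 250 bp only of a record that was itself merged. At a global IDR of 0.001 the list held 2658 peaks, of which 65.0% were in all 3 own lists, and with 50% reciprocal overlap the share was 24.1%.

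Promoters held 45.1% of summits, 3.32 times the 13.6% of shuffled positions (permutation p = 0.002, the smallest possible). The own lists gave 46.3% ± 2.60 (SD, n = 3). Coding exons held 0.503% against 13.7% shuffled, 3' UTRs 1.11% against 4.43%, and intergenic sequence 12.6% against 27.2% (adjusted permutation p = 0.0035 for each). Introns held 39.2% against 39.5% (adjusted permutation p = 0.886), and 5' UTRs and non-coding exons also did not pass the test. Shuffled positions left out assembly gaps but not sequence where reads cannot be placed. The part of such sequence in these differences was not separated. Of the 2150 promoter summits, 72.6% lay upstream of the nearest TSS, with a median position of -110 bp.

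**Figure D1:**
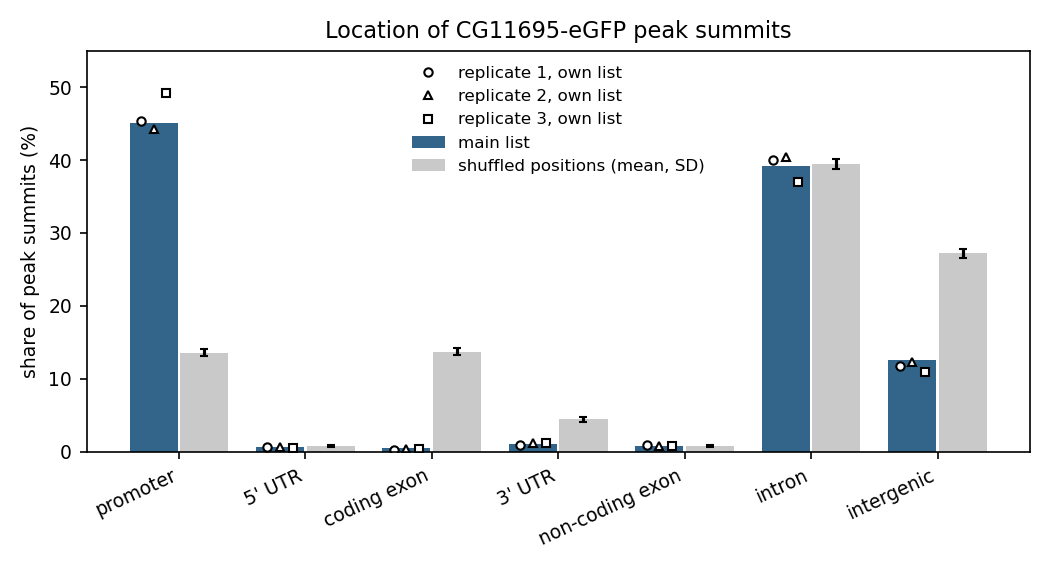
Share of peak summits (%) in each location class for the main list (blue bars), for shuffled positions (grey bars, mean and SD of 1000 shuffles) and for each replicate's own list (open symbols). Promoters held 45.1% of main summits and 13.6% of shuffled positions, and coding exons 0.503% and 13.7%.

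The median signal was slightly higher at promoters than elsewhere. The median was 124 at 2150 promoter peaks and 118 at 2620 other peaks, a difference of 0.07 on the log2 scale (permutation p = 0.0182, two-sided). The size depended on the list: it was 0.19 in each of the other pair lists and 0.20 at a global IDR of 0.001. With the left-out records added back it was 0.06 (permutation p = 0.0497). The promoter share did not fall steadily with signal. In 5 equal classes of signal after merging, a division chosen after seeing the data, it was 56.5% in the strongest, 37.6% in the middle and 49.9% in the weakest class.

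Peaks were spread over all arms, and chromosome 4 alone had a call that held under all 7 alternatives run. Arm 4 held 21 peaks, 0.442 times the number its length gives (exact binomial test, adjusted p = 0.000171). By the same exact test, arm 3R held 0.909 times (adjusted p = 0.00118), arm 3L 1.07 times (adjusted p = 0.0296) and X 1.08 times (adjusted p = 0.0228) the number given by length. Arms 2L and 2R, at 1.04 and 0.960, did not pass the test. The arm lengths likewise left out gaps alone, so sequence where reads cannot be placed counts in them. Over the own lists the ratio for arm 4 was 0.315 ± 0.122 (SD, n = 3). The calls on 3L, 3R and X were lost when 126 records past the score threshold that the thresholded list leaves out, mostly on 3R, were added back (1.04, 0.955 and 1.05 times, exact test, adjusted p = 0.119 for each), and X also lost it in the pooled list (1.03 times, adjusted p = 0.372). By the exact test 2R passed as lower in each of the other pair lists, at a global IDR of 0.001 and by number of TSSs (0.879 to 0.937 times, adjusted p from 3.50e-05 to 0.0496), while 2L passed as higher without replicate 1 and at a global IDR of 0.001 (1.08 times in each, adjusted p = 0.0320 and 0.0469) and as lower by number of TSSs (0.939 times, adjusted p = 0.0389).

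A peak stood within 500 bp of a TSS at 2257 of 13945 protein-coding genes (16.2%). Genes at divergent promoters had one more often: 1141 of 4648 (24.5%) against 1116 of 9297 others, an odds ratio of 2.39 (Fisher's exact p = 1.69e-76). In the own lists the shares were 17.2% ± 1.98 and 8.07% ± 0.953 (SD, n = 3), with odds ratios from 2.12 to 2.57. Much of this is built in, since a single summit between a divergent pair counts for both genes. When peaks were moved to genes drawn with equal chance, at the same offset from the TSS, the odds ratio was 1.79 ± 0.105 (SD over 1000 placements, highest 2.16), below the 2.39 observed (one-sided permutation p = 0.001, the smallest possible; 0.001 to 0.007 in the own lists). These placements drew from all protein-coding genes. Among the 10427 genes with a peak in the ranked list, the observed odds ratio was lower, at 1.80 (Fisher's exact p = 1.35e-34). Placements were not run on that background, so an excess beyond double counting was not tested there.

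Cytoplasmic ribosomal protein genes were the list with peaks most often. A peak stood at 58 of 93 members (62.4%) against 15.9% of other genes, an odds ratio of 8.78 (Fisher's exact, adjusted p = 1.94e-22), and at 39.4% ± 2.24 of members in the own lists (SD, n = 3). RpL34b (3R, 9401296 to 9401516), RpL32 (3R, 30046172 to 30046443), RpS20 (3R, 20821910 to 20822112) and RpL7 (2L, 10200943 to 10201118) had the highest signals of this list, 379, 367, 331 and 291. These were below the strongest peaks of the genome, with ranks of 357 for RpL34b and 564 for RpL7.

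Gene families of the cuticle and of chemical sensing had no peak within 500 bp of a TSS in the main list. None of 123 cuticular protein genes had one (adjusted p = 4.09e-09, Fisher's exact), and none of 179 odorant and gustatory receptor genes (adjusted p = 2.52e-13, Fisher's exact). The test takes each gene as independent, and neighbouring members of a family were not merged into clusters. The receptor list also took in ionotropic receptor genes, and its 179 members include them. In the own lists the cuticular share was 0.271% ± 0.469 (SD, n = 3), and it was 0.813% in each of the other pair lists. Within 1000 bp of a TSS, 4.07% of cuticular and 1.68% of receptor genes had a main peak, and both lists still passed as lower (Fisher's exact, adjusted p = 6.38e-06 and 3.07e-12). Osiris genes had 0 of 25 (4.0% without replicate 3) and did not pass Fisher's exact test (adjusted p = 0.131), except with promoters of 1000 bp (adjusted p = 0.0469).

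None of the other 17 lists passed the adjusted Fisher's exact test in the main list, and the insulator list passed in 1 of the 3 own lists. Among insulator and architectural protein genes, 6 of 19 had a peak, including Chro, Cp190 (3R, 15275256 to 15275530, signal 579), Trl, which encodes GAGA factor (signal 255 near a TSS), and Ibf2 (signal 152), with an adjusted p of 0.324. Among Polycomb and trithorax group genes, 6 of 19 had one, including ph-p (X, 2137191 to 2137522, signal 1226), brm (signal 668), E(z) (signal 515) and ph-d (signal 95.3). Heat shock genes had 6 of 19, led by Hsp27 (3L, 9383774 to 9384048, signal 801), Hsp26 (signal 285), the mitochondrial chaperone gene Hsc70-5 (signal 277) and Hsp22 (signal 272). DNA replication and cell cycle genes had 7 of 28, including CycE (signal 274), RnrS (signal 245), dpa (signal 180) and Cdk1 (signal 152). Germline and piRNA pathway genes had 5 of 33, including papi (signal 609), cuff (signal 257), bgcn (signal 160.0) and piwi (signal 145). Of the genes named so far in these lists, ph-d, Hsp22 and bgcn had a peak in 1 replicate's own list. For dpa and piwi it was 2 own lists, and for the others all 3. Enhancer of split genes had 3 of 11, namely E(spl)m3-HLH, E(spl)m7-HLH and E(spl)mdelta-HLH, with signals of 292, 214 and 155. Their share was higher in each own list, at 36.4%, than the 27.3% of the main list.

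Hox genes had 3 of 8 (37.5%), at Dfd, Antp and Scr with signals of 85.3, 69.0 and 68.3, and none of these was in a replicate's own list. The Hox share was 0% without replicate 3 and 25% without replicate 1. Segmentation genes had 2 of 25, hry (signal 80.9) and slp2 (signal 71.9), and dorsoventral patterning genes 3 of 19, ush, rho and sog (signals 106, 106 and 69.3). Neural genes had 3 of 26: elav, a pan-neuronal RNA-binding protein gene (X, 523347 to 523642), had a signal of 828 and was in all 3 own lists, while pros and insc had 69.9 and 68.9. Without replicate 1 the share fell from 11.5% to 3.85% for neural genes and from 10% to 5.0% for muscle genes, and the muscle share was 15% without replicate 3. Glial genes had 2 of 9, moody (signal 396) and Gli (signal 248), and muscle genes 2 of 20, sls (signal 234) and Tm1 (signal 79.7). The gut and fat body list had fkh (signal 230) of 13 members, and the haemocyte list had ush of 11. Proteasome genes had 4 of 48, led by Rpn3 (signal 241) and Prosbeta2 (signal 124), and oxidative phosphorylation genes 9 of 86, led by ND-ASHI (signal 395), ND-MWFE (signal 261), ND-24 (signal 181) and ND-51 (signal 140). Besides the Hox genes, slp2, sog, pros and Tm1 had no peak in a replicate's own list, and rho and insc had one in 1. For hry, ush and Prosbeta2 it was 2 own lists, and for the other non-Hox genes named here all 3.

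**Figure D2:**
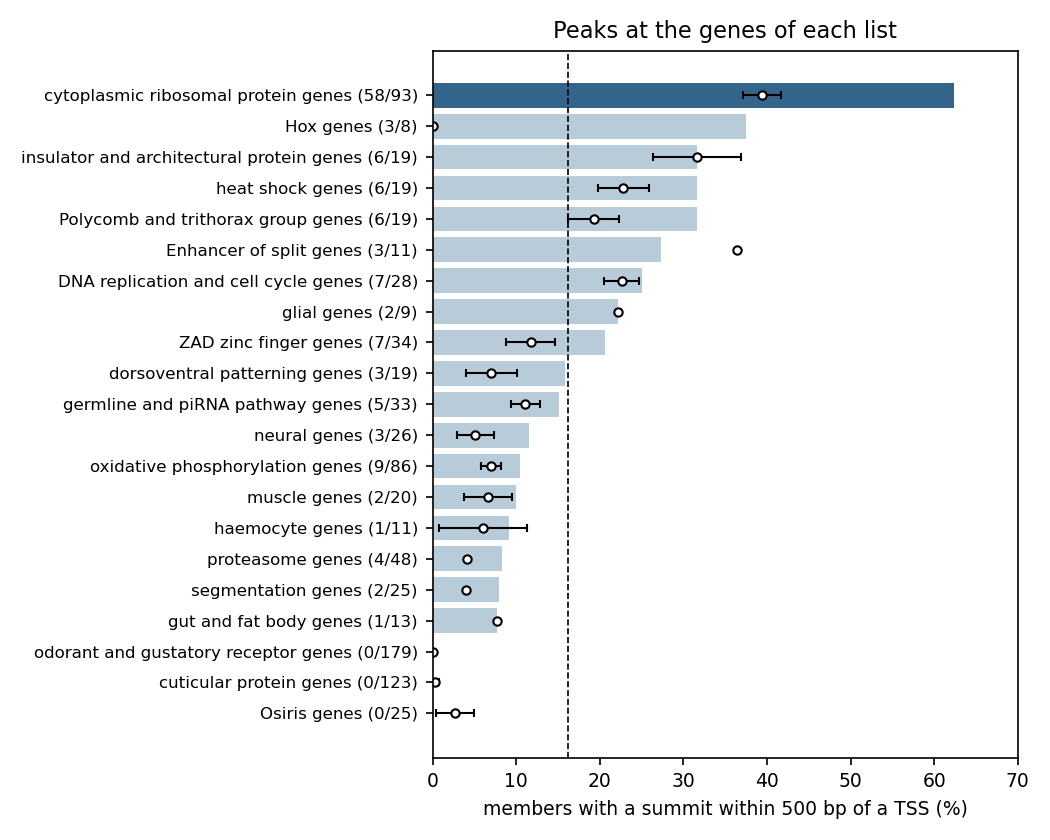
Share of the members of each gene list (%) with a summit within 500 bp of a TSS; bars show the main list, dark where the adjusted Fisher's exact test was passed with at least 1 peak, and open points show the mean and SD of the 3 own lists. The dashed line marks the 16.2% of all protein-coding genes, and cytoplasmic ribosomal protein genes reached 62.4%.

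The tagged gene itself carried a moderate peak. CG11695 (X, 11576883 to 11578806, plus strand) had 1 peak within 1000 bp, with its summit at 11576695, 188 bp upstream of the TSS. Its signal was 133 and its rank 2076 of 4770. It was in the own list of replicate 1, at rank 1542, and not in those of replicates 2 and 3. The tagged transgene adds copies of this locus, which can add to the signal here, so this peak does not show binding of the protein to its own gene. Of the ZAD zinc finger genes, the family of CG11695, 7 of 34 had a peak (adjusted p = 0.725, Fisher's exact), led by CG3032 (signal 204) and M1BP (signal 152), and including idc (signal 104). The 7 include CG11695 itself, and idc shares its summit with trem, another of the 7. CG3032 and M1BP had a peak in 2 own lists each, and idc in 1.

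Summits lay in AT-rich sequence. The 200 bp around summits had 36.1% GC against 42.2% at shuffled positions (permutation p = 0.002, the smallest possible), and 34.8% ± 0.799 in the own lists (SD, n = 3). The repeat-masked share was 22.5% against 20.1% shuffled (permutation p = 0.002). The excess of masked sequence was 2.36 percentage points against shuffled positions and 6.08 against sites matched on distance to a TSS.

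**Figure D3:**
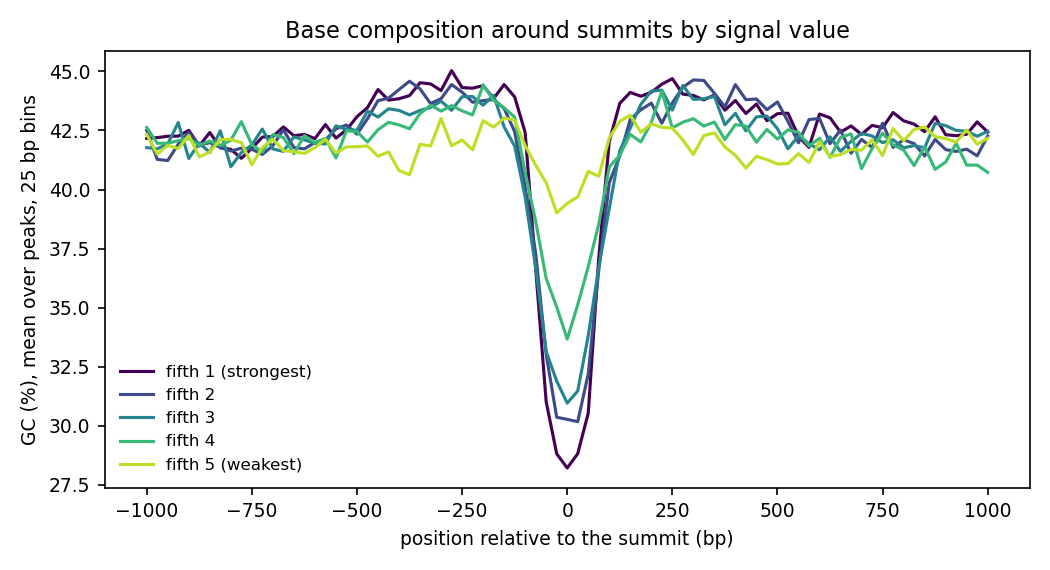
GC (%) in 25 bp bins against the position relative to the summit (bp), as the mean over peaks in each of 5 equal classes of signal, with summits within 250 bp merged. Over the central 200 bp the mean was 32.8% in the strongest class and 40.4% in the weakest.

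Of 758 short sequences found on 2L, 2R and 4, 706 passed on the other arms, and 657 of these held at most 1 G or C. The leading one, AAATAT, was present at 34.7% of tested summits and 14.9% of their flanks (one-sided exact McNemar test, adjusted p = 2.13e-66). Over the whole list its share was 34.2%, and 36.7% ± 1.20 in the own lists (SD, n = 3). The position matrix built from the leading sequence of 8 bases, TATTTTAA, held G or C at a single position, with 52 occurrences. Among sequences with more G and C, ACAGTG was at 6.91% of summits and 4.19% of flanks (exact test, adjusted p = 2.66e-06). Against shuffled copies of the same windows that kept dinucleotide counts, a control chosen after seeing the data, 70 sequences passed. AAATAT led here too, at 34.7% of tested summits and 23.3% of copies (one-sided exact McNemar test, adjusted p = 3.41e-25). At most 1 G or C was held by 30 of the 70. Of the 70, 13 contained GAGCG, GCGAG or GAGAG and 8 contained CAGTG, each counted with its reverse complement, against 1 and 2 of the 706 that passed against flanks. Both groups were singled out after the values were seen.

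Of the 13 known motifs, 8 differed between summits and flanks. The TATA consensus was at 572 of 4770 summits and 346 flanks (exact McNemar test, adjusted p = 4.01e-14). By the same exact test, the DRE was at 1.61% and 0.713% (adjusted p = 0.000255), motif 1, bound by M1BP, at 0.881% and 0.398% (adjusted p = 0.0116), motif 7 at 3.69% and 2.70% (adjusted p = 0.0139), and the su(Hw) core at 1.89% and 1.26% (adjusted p = 0.0286). The Pho core, CTCF core and motif 5 E-box were rarer at summits, at 6.79%, 5.72% and 4.23% against 8.51%, 7.21% and 5.43%. Of the 8 calls, only those of TATA, the Pho core and the CTCF core held under all 8 alternatives run. Summits and flanks differed in GC, and no control that kept base composition was run for the motifs. The part of composition in the calls was therefore not separated in any of these 8 alternatives. Motif 1 and the motif 5 E-box each lost the call under 5 of them (exact test, without replicate 1 adjusted p = 0.160 for motif 1, without replicate 3 adjusted p = 0.0763 for motif 5), the DRE under 3, and motif 7 and the su(Hw) core under 2 each. Against sites matched on distance to a TSS, the DRE and motif 5 E-box did not pass (exact test, adjusted p = 0.728 and 0.262). Position near a TSS was therefore not separated for them. The other calls held against these sites. The GAGA motif and the long GA repeat, without a call in the main list, passed as rarer at summits without replicate 3 (3.72% and 0.504%, exact test, adjusted p = 0.000116 and 0.0297) and without replicate 1 (4.09% and 0.567%, adjusted p = 0.0011 and 0.0297), and as more frequent than at sites matched on distance to a TSS (adjusted p = 7.71e-07 and 0.0135).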

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

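All values in this part were chosen after seeing the data, and no explanation was tested for them. The ranked list behind the main list held 126 records past the score threshold that the thresholded list leaves out, a signal in data that the main values above do not use. The accompanying text notes name a further source for the thresholded lists than for the ranked ones, and its content is not given in the sources used here. Whether these records were removed on purpose is therefore not known. They were unevenly placed, with 81 on 3R and 30 on 2L of 125 distinct summits on the arms. Of these 125, 65 (52.0%) were promoter peaks, none lay in an annotated transposon, and their median signal was 116 against 120 in the main list. The strongest were intronic peaks nearest to cbt (2L, 480910 to 481274, signal 1859) and Lk6 (3R, 11760895 to 11761215, signal 1279), then promoter peaks at CG18428 (signal 1184) and larp (signal 978). The genes were named after their values were seen. The cbt record would have ranked among the strongest of the main list.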

How the results depend on the processing

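Among the tests in this part, a global IDR of 0.001, merged summits, added-back records, shuffled copies, peaks moved to other genes and single pairs of the signal correlation were chosen after seeing the data. Of 93 alternative values of the main results, 84 kept their direction and side of the threshold, or stayed within 1.5 times for counts and within 1 SD between pairs for the signal correlation, and none reversed. The planned global IDR of 0.01 removed no peak, so it tests nothing and is not counted here. The overlap with all own lists is not counted either, since its test is built in; its share was 24.1% to 65.0% over 8 alternatives. The alternatives named without replicate 1 or 3 leave it out of the IDR comparison only, as the main list does with replicate 2, because all pair lists hold peaks and signals of pooled libraries. A global IDR of 0.001 left 2658 peaks. With the left-out records added back, 1 arm passed the exact test in place of 4. The enriched sequences numbered 1126 within 100 bp, 1160 when found on 3L, 3R and X, and 70 against dinucleotide-shuffled copies. Known motifs that passed numbered 5 in the pooled list and 5 within 50 bp. Mean rho was 0.726 for peaks past the threshold, and 0.296 to 0.322 for single pairs without replicate 1, 2 or 3 in turn. Single motifs and arms were less stable: of 350 values for single classes, arms, lists and motifs, 19 lost the threshold, 16 gained it and 5 reversed. Motif 1 lost its call with the direction reversed at a global IDR of 0.001 (0.414% of summits, exact test, adjusted p = 0.690) and within 50 bp (0.252%, adjusted p = 0.930). The GAGA motif gained a call as rarer in 5 alternatives and the long GA repeat in 2, and both passed in the reversed direction against sites matched on distance to a TSS (4.82% and 0.860%, exact test, adjusted p = 7.71e-07 and 0.0135). Arm 2L passed in the reversed direction by number of TSSs (0.939 times, exact test, adjusted p = 0.0389). The cause was not tested. No paired analysis was possible because there was 1 group. Depth was unknown, so its limits could not be set.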

Other observations

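In this part, the mitochondrial ribosomal protein list, the division of peaks by signal, the choice of CAGTG, the shuffled copies and the test on non-promoter peaks were chosen after seeing the data. CAGTG was singled out after the shares of 5 short sequences by signal and the sequences of several subsets of peaks had been looked at.

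Mitochondrial ribosomal protein genes supplied several of the strongest peaks, and the group did not pass the test. A peak stood at 17 of 73 members (23.3%) against 16.1% of other genes, an odds ratio of 1.58 that did not pass (Fisher's exact p = 0.110), and at 16.4% ± 2.37 in the own lists (SD, n = 3). The highest signals were at mRpL41 (1473), mRpS23 (1382), mRpS10 (1292) and mRpL23 (827), and the mRpS23 summit is the one named above for CenG1A.

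The low GC at summits was set against 2 technical explanations. Distance to a TSS alone was argued against. Compared with sites matched on it, the GC share at peaks differed by -6.42 percentage points (permutation p = 0.0198, the smallest possible). The matched sites fell on either side of a TSS at random, while 72.6% of promoter summits lay upstream. A lower GC on the upstream side of promoters was therefore not separated. Repeat-masked sequence as the only source was also argued against, for the 616 peaks without a masked base (12.9% of the list). These lay below shuffled sites without one (43.3% against 48.6%, a difference of -5.22 points, permutation p = 0.002, the smallest possible). The shuffled sites were not matched on location class, and coding exons held 0.503% of summits against 13.7% shuffled. The rarity of coding exons at peaks was therefore not separated. Fragmentation, amplification and mapping bias stay open, because no input library was analysed here. No biological explanation was tested.

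The sequence CAGTG was less frequent at strong peaks, at 12.1% of the strongest of 5 equal classes of signal and 23.0% of the weakest after merging. Base composition may account for this: relative to dinucleotide-shuffled copies the strongest class differed from the weakest by -0.0919 on the log2 scale (95% bootstrap interval -0.41 to 0.21). In each class CAGTG was 1.62 to 1.95 times as frequent as in the copies, while over the whole list it was at 18.2% of peaks and 17.2% of flanks. A larger share of promoters among strong peaks was argued against, since among non-promoter peaks the odds ratio of CAGTG in the strongest against the weakest class was 0.617 (15.1% against 22.4%, Fisher's exact p = 0.00774). No biological explanation was tested.

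The peaks at cytoplasmic ribosomal protein genes could come from a signal that strongly transcribed genes give in any precipitation. The test used tRNA genes, of which 22 of 174 clusters (12.6%) had a peak against 16.2% of protein-coding genes, an odds ratio of 0.750 (Fisher's exact p = 0.253). This did not decide the question, since the difference was within its error and repeated tRNA copies can be lost in mapping. The tRNA genes are also transcribed by another polymerase than ribosomal protein genes, and transcription was not measured here. The explanation stays open, and no control precipitation was analysed here.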
